A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

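RNA was sequenced from 6 cultures of *Saccharomyces cerevisiae*: 3 biological replicates of CX01F, an evolved strain, and 3 of CX01, its parent. Per the labels, the cells were grown overnight in YPD, a rich medium, kept for 16 h in Delft medium, a defined minimal medium, and moved to Delft medium in which 1% methanol replaced glucose. They were collected at an OD600 near 1.0 from shake flasks held at 30 °C and 200 rpm. Both strains carry the same genotype label, which lists introduced genes for methanol and xylose use, PEX5, MDH2, MDH3 and NDE1, and deletions of PEX31 and PEX32. The labels call the replicates biological and give no sequencing batch, date or library kit. The p-values set the strain difference against the spread within the 3 cultures of each strain as they were handled. A batch or handling difference between the strains cannot be told apart from the strains themselves.

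The authors deposited a table of whole-number read counts per gene, not normalized. The submitters' processing notes name TopHat2 2.0.12, Cufflinks, featureCounts and Subread 1.4.6, without saying what each one did. The genome build, the annotation, the strand setting and the treatment of reads that map to several places were not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense pairs are therefore uncertain, since their reads may have been split or shared. Among the genes named, this touches the ribosomal proteins RPS22A and RPL37A, which have close copies, and TDH1 and SAM1, which have similar ones. It also touches SPS100, PHO84 and MET17, which overlap another gene or transcript in the RefSeq R64 gene table.

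The table has 6401 rows. One row without a gene name held 0.0392% to 0.044% of the counts in the CX01 libraries and 0.00877% to 0.00916% in the CX01F libraries, and it was kept out of library sizes and tests. Of the 6400 genes, 96 had 0 counts in all 6 libraries. Library totals ranged from 51537969 to 63183824 counts, so 3 counts, the upper limit that a count of 0 allows, correspond to 0.0475 to 0.0582 CPM, taken on these totals without TMM scaling. This limit covers counting error only, and the counts carry no molecular identifiers.

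Gene names were matched to the RefSeq R64 gene table by symbol, systematic name or unambiguous synonym. The match covered 6083 of the 6400 genes and 5908 of the tested genes. Because the authors' build is not given, R64 was used only for names, chromosomes, coding lengths, GC content, neighbours and overlaps, and no coordinates are printed.

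Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at its settings (a minimum count of 10 and a minimum total of 15), which left 6129 tested genes and took out 271. Libraries were scaled by TMM, and CX01F was compared with CX01 by the quasi-likelihood test (glmQLFit and glmQLFTest, strain as the only term, 4 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the tested genes. A gene was called changed at an adjusted p under 0.05. Log2 fold changes are CX01F minus CX01, their standard errors (SE) are the fold change divided by the square root of the quasi-likelihood F, and levels are CPM on the TMM-scaled library size, as mean ± SD over 3 libraries. Log2 changes are relative to the TMM scaling, which takes the bulk of genes as unmoved.

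Before the data were examined, 36 gene lists were fixed. They cover central carbon metabolism (methanol and formaldehyde oxidation, aldehyde dehydrogenases, glycolysis, gluconeogenesis and the glyoxylate cycle, the tricarboxylic acid cycle, the pentose phosphate pathway, xylose and polyol metabolism, hexose transport and carbon source regulators), respiration and peroxisomes, stress and storage, ribosomes, biosynthesis, nutrient regulons, the cell wall, the cell cycle, mating type, sporulation and auxotrophic markers. The mitochondrially encoded list has no row in the table used and was not analysed here, so 35 lists with at least 4 tested members were tested. The introduced genes for methanol and xylose use have no row either and were not analysed here. The list of cytosolic ribosomal proteins was taken by symbol pattern and also holds RPP1, a subunit of RNase P. Each list was tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, and again with the correlation estimated per list and with fry. Counts of members are adjusted over all tested genes. The counts adjusted over the list alone were the same as these in each of the 35 lists.

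The genes named were chosen by a rule also fixed before the data were examined: the genes of the genotype label that the table lists; the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 CPM and no overlap between the strains' libraries; the 2 called members of largest absolute change, at 10 CPM or more, of the 8 lists with the smallest camera p; and 1 such member of each other list. ALD4, FDH1, FDH2, SFA1, YJL068C, TKL1 and the genes that the closing section names outside this rule were chosen after their values were seen.

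Replicates were compared by Pearson correlation of log2 CPM and by a chi-square of their counts. Within a strain the correlations were 0.998 to 0.9987 and the chi-square per degree of freedom was 2.41 to 19, so no pair of libraries agreed within sampling noise. The spread was still small, with a biological coefficient of variation of 2.85% by edgeR, and the small p-values rest on it. Deviations from the strain means of same-numbered replicates correlated at 0.0242, 0.0785 and 0.0207, so the numbers were not taken as pairs.

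The edgeR step was tested on simulated counts for the same comparison, with 6124 genes tested and 50 changed genes at each log2 size. It recovered 90% of genes changed by 0.25 and 100% of those changed by 0.5, 1 and 2, with 8 false calls (3.94% of the calls). The simulation left most genes unmoved and changed equal numbers up and down, so it does not test the scaling. Its share of false calls may not carry over to these data, where most genes were called. The alternatives were RLE size factors, library size only, no filter on low counts, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma voom, leaving out the 20 most abundant genes, the replicate number as a block, leaving out each library, glmTreat, an estimated correlation or fry for the lists and, added after seeing the data, leaving out the genes of chromosomes XI and XV. Figures were drawn with matplotlib 3.10.9.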

Results

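The series compares the evolved *S. cerevisiae* strain CX01F with its parent CX01, to ask how the cells rearranged their metabolism while adapting to growth on methanol. Each strain has 3 libraries of read counts per gene, with totals of 51537969, 63183824 and 56237312 counts in CX01 and 58360225, 52849030 and 62826253 in CX01F. Between 6232 and 6272 genes had counts in a library. The most abundant gene was ALD4, a mitochondrial aldehyde dehydrogenase, in CX01 (1.43% to 1.52% of counts) and GAL2, the galactose permease, in CX01F (2.03% to 2.06%). Correlations of log2 CPM across genes were 0.998 to 0.9987 within a strain and 0.882 to 0.887 between strains.

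The genes of the genotype label, which is the same for both strains, were looked at first. PEX31, labelled as deleted, had 0 counts in each CX01 library and 0 or 1 count in each CX01F library, where a count of 0 allows up to 0.0582 CPM. PEX32, also labelled as deleted, had 167 to 279 counts in each library of both strains, 3.57 ± 0.318 CPM in CX01F and 4.13 ± 0.438 CPM in CX01 (log2 fold change -0.21, SE 0.106, edgeR adjusted p = 0.082). Its call turned on single libraries, with an adjusted p of 0.0465 without CX01 replicate 2 and 0.0384 without CX01F replicate 3, on scaling by library size only (log2 -0.41, adjusted p = 0.00215) and on leaving out the genes of chromosomes XI and XV, an alternative added after seeing the data (log2 -0.32, adjusted p = 0.011). MDH2, the cytosolic malate dehydrogenase, was 18.5-fold higher in CX01F (6951 ± 11.7 against 376 ± 14.3 CPM, log2 4.21, adjusted p = 8.98e-19). NDE1, an external NADH dehydrogenase of mitochondria, was 1.9-fold higher (log2 0.93), and MDH3, the peroxisomal malate dehydrogenase, rose by a log2 of 0.35. PEX5, the receptor for peroxisomal import, fell by 0.24 on the log2 scale. With library size only the log2 changes of MDH3 and PEX5 were 0.15 and -0.45. The counts give no separate values for native and added copies of these genes.

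The strains differed at most tested genes. Of 6129, the edgeR quasi-likelihood test called 5603 (91.4%), 2787 higher and 2816 lower in CX01F, and 526 did not pass. The median absolute log2 change of the called genes was 0.68. A change of at least 2-fold was seen in 1878 genes (985 higher, 893 lower) and of at least 8-fold in 136 (67 higher, 69 lower). All 3 CX01F libraries lay on one side of all 3 CX01 libraries for 5631 genes (91.9%), where chance gives 10%. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1. The balance of directions rests on the scaling: with library size only, 2221 genes were higher and 3407 lower.

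The largest rise was in GAL2, at 21980 ± 186 CPM in CX01F and 32.5 ± 13.9 CPM in CX01 (677-fold, log2 9.40, SE 0.272, adjusted p = 1.24e-13). ADH6, an NADPH-dependent alcohol dehydrogenase, rose 102-fold (log2 6.67), and ICL1, the isocitrate lyase of the glyoxylate cycle, rose 99.4-fold to 10964 ± 43.5 CPM (log2 6.63). YDR010C rose by a log2 of 6.51, from 2.51 ± 0.165 to 229 ± 2.17 CPM. It lies next to GAL3 in R64, and the strand setting of the counts is not given. YLR307C-A rose 85.8-fold (log2 6.42) to 4714 ± 136 CPM.

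The largest fall was in SPS100, a spore wall gene, from 1579 ± 78.9 CPM in CX01 to 25.3 ± 0.664 CPM in CX01F (62.5-fold lower, log2 -5.97, adjusted p = 2.32e-19). SPS100 overlaps a noncoding transcript in R64. SIP18 and GRE1, both hydrophilins induced by osmotic stress and desiccation, were 39.3-fold and 31.8-fold lower (log2 -5.29 and -4.99). CHA1, the catabolic serine deaminase, was 26.7-fold lower (log2 -4.74). YMR175W-A, which neighbours SIP18, was 25.6-fold lower (log2 -4.68).

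**Figure D1:**
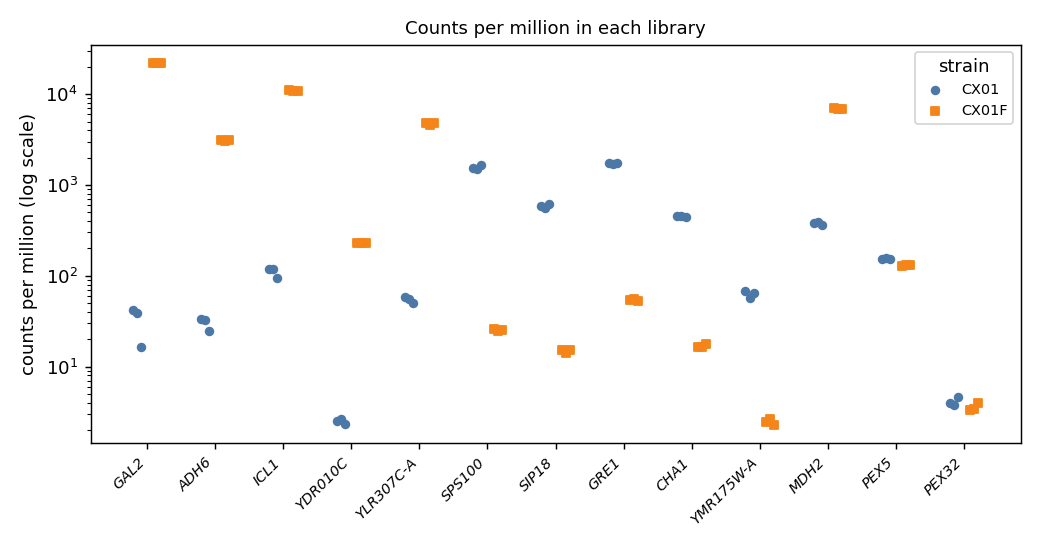
CPM, on a log scale, of the 5 genes with the largest rise, the 5 with the largest fall and MDH2, PEX5 and PEX32, with 1 point for each of the 3 libraries of CX01 (circles) and CX01F (squares). GAL2 lies near 21980 CPM in CX01F against 32.5 CPM in CX01, and the PEX32 points of the strains overlap.

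Coding genes of chromosomes XI and XV lay apart from the rest. Their median log2 change was -0.82 on XI (315 genes) and -0.86 on XV (536 genes), against medians of 0.02 to 0.26 on the other 14 chromosomes. On these 2 chromosomes 677 of 851 coding genes (79.6%) were lower in CX01F, and elsewhere 39.3% were. Without the genes of both chromosomes, an alternative added after seeing the data, 4784 genes were called, 2344 higher and 2440 lower. Of the genes named in this section, ALD4, MDH2, FDH1, GCY1, FAA1, GAC1, HIS3 and ADE2 are on XV and RGT1, MRP49, DAL80 and STE3 on XI.

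**Figure D2:**
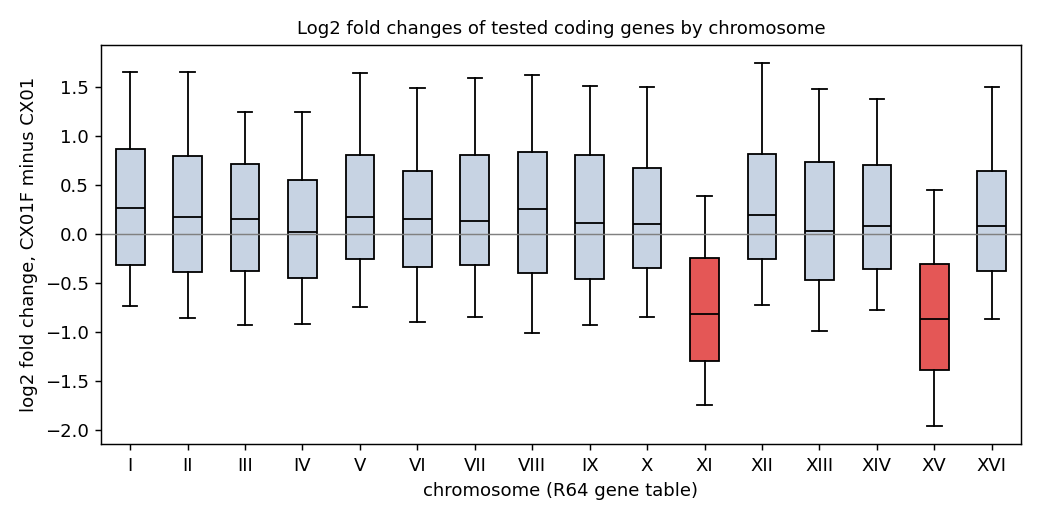
Log2 fold change, CX01F minus CX01, of the tested coding genes of each of the 16 chromosomes; boxes span the 25th to 75th percentiles with the median as a line, and whiskers reach the 10th and 90th percentiles. The medians of XI (-0.82) and XV (-0.86), in red, lie below the other 14, which range from 0.02 to 0.26.

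Camera called 17 of the 35 tested gene lists, 14 higher and 3 lower in CX01F. None of the 17 held with a correlation estimated from the libraries, where the lowest adjusted p was 0.0724. The estimates for these lists ranged from -0.00948 (peroxisome biogenesis) to 0.614 (cytosolic ribosomal proteins). For the tricarboxylic acid cycle the estimate (-0.00848) was below the preset 0.01, yet the unadjusted camera p rose from 4.61e-07 to 0.00556. A lost call therefore need not mean that the members of a list are correlated. With the preset correlation, camera also called 13 to 18 lists in the 9 other ways of dividing the 6 libraries into 3 and 3. These mix the strains unequally and so keep part of the strain difference. The number of list calls therefore cannot separate the strain grouping from other groupings. The counts of called members are therefore given for each list.

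Genes of respiration and the tricarboxylic acid cycle rose together. All 17 genes of the cycle were higher (camera adjusted p = 3.23e-06, adjusted p = 0.0724 with an estimated correlation), led by FUM1, fumarase, at log2 3.59 and CIT1, citrate synthase, at 2.68. In the respiratory chain 22 of 25 nuclear genes rose and 3 fell (0.000116, and adjusted p = 0.481 with an estimated correlation), among them CYC1, cytochrome c, at 2.87 and QCR2, a subunit of complex III, at 2.23. For ATP synthase 15 of 17 rose and 1 fell, with ATP5 at 2.38 (0.000423, and adjusted p = 0.481 with an estimated correlation). Of the 14 genes of gluconeogenesis and the glyoxylate cycle, 11 rose and 2 fell, with a median log2 change of 3.30 (0.00199, and adjusted p = 0.137 with an estimated correlation), and ICL1 changed most.

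Glycolysis moved the other way. Of 20 genes, 15 fell and 5 rose (camera adjusted p = 0.0159, adjusted p = 0.496 with an estimated correlation), with a median of -0.59, or -0.40 without chromosomes XI and XV. TDH1, a glyceraldehyde-3-phosphate dehydrogenase, was 14.2-fold lower (log2 -3.83). The alcohol and formate dehydrogenases taken as the methanol and formaldehyde oxidation list were not called as a list (4 higher, 8 lower of 12, camera adjusted p = 0.516). Their median (-0.29, or -0.15 without chromosomes XI and XV) and mean (0.19) differ in sign, with ADH6 changing most. Within this list the formate dehydrogenases FDH1 and FDH2 were at log2 -2.13 and -2.76 and SFA1 at -0.93, while YJL068C was at 0.80. Aldehyde dehydrogenases and acetyl-CoA synthetases (6 higher, 2 lower) were not called either (0.222), with ACH1, an acetyl-CoA hydrolase, at log2 3.13. The pentose phosphate list had 8 higher and 3 lower of 12 (0.172), with TKL2, a transketolase, at -3.86 and TKL1, also a transketolase, at 2.99. Xylose and polyol metabolism had 7 higher and 6 lower of 16 (0.879), with GCY1, a glycerol dehydrogenase, at 3.54. Hexose transporters and sensors had 7 higher and 8 lower of 18 (0.78), with a mean of 0.32 and a median of -0.04, which turned to 0.07 without chromosomes XI and XV, and GAL2 changed most. Carbon source regulators had 9 higher and 16 lower of 26 (0.309), with RGT1, a repressor of hexose transporter genes, at -1.87.

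Ribosomal protein genes rose almost throughout. Of 138 genes 135 rose and 2 fell, with a median log2 change of 2.09 (camera adjusted p = 9.78e-24, adjusted p = 0.362 with an estimated correlation), RPS22A at 3.16 and RPL37A at 2.87. Both have near-identical copies, so their own values are uncertain. In ribosome biogenesis 89 of 107 rose and 12 fell (8.65e-08, and adjusted p = 0.491 with an estimated correlation), among them NOP1, the fibrillarin methyltransferase, at 2.46 and NSR1 at 2.44. Mitochondrial ribosomal proteins went both ways (19 higher, 34 lower of 66, camera adjusted p = 0.139), with MRP49 at -1.88, and this list was called lower with library size only (0.0258).

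Biosynthetic lists rose. All 15 purine genes were higher (camera adjusted p = 1.59e-05, adjusted p = 0.0724 with an estimated correlation), with GUA1, GMP synthetase, at log2 3.11 and ADE12 at 2.79. Of 37 genes of arginine, lysine, leucine and histidine synthesis 32 rose and 3 fell (8.65e-08, and adjusted p = 0.0724 with an estimated correlation), with LEU4 at 3.58 and ARG4 at 2.93. Ergosterol genes rose in 23 of 26 cases and fell in 3 (6.02e-05, and adjusted p = 0.0724 with an estimated correlation), with ERG26 at 2.11 and ERG3 at 2.08. Sulfur and methionine metabolism had 23 higher and 8 lower of 31 (0.00757, and adjusted p = 0.245 with an estimated correlation), with SAM1 at 3.97. Folate one-carbon and glycine cleavage had 13 higher and 4 lower of 18 (0.0226, and adjusted p = 0.199 with an estimated correlation), with GCV1 at 2.81. All 7 auxotrophic marker genes rose (0.00735, and adjusted p = 0.175 with an estimated correlation), with MET17 at 2.93. Of these, LYS2, LEU2, HIS3, MET17 and ADE2 also belong to the amino acid, sulfur or purine lists above, so this list is not separate from them. MET17 overlaps another gene in R64.

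Nutrient regulons divided. Phosphate genes rose in 14 of 16 cases (camera adjusted p = 0.000183, adjusted p = 0.12 with an estimated correlation), with PHO84, a high-affinity phosphate transporter, at log2 4.05. PHO84 overlaps a noncoding gene in R64. Iron genes had 22 higher and 7 lower of 29 (0.000542, and adjusted p = 0.208 with an estimated correlation), with FET3, a multicopper oxidase of iron uptake, at 3.84. Zinc and copper genes had 7 higher and 4 lower of 12 (0.293), with CTR3 at 1.62. Nitrogen catabolite repressed genes had 10 higher and 15 lower of 27 (0.518), with DAL80 at -4.25.

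Most chaperone and peroxisome biogenesis genes fell. Of 26 chaperone and heat shock genes 25 were lower and 1 higher, with a median log2 change of -1.50 (camera adjusted p = 8.65e-08, adjusted p = 0.208 with an estimated correlation). HSP12, a membrane-associated small heat shock protein, was 18.9-fold lower at 287 ± 3.64 against 5418 ± 274 CPM, and HSP26 was 18.6-fold lower. Of 31 peroxisome biogenesis genes 23 fell and 5 rose (0.00594, and adjusted p = 0.137 with an estimated correlation), with a median of -0.41, or -0.30 without chromosomes XI and XV. Against that direction PEX21, which acts in import of the PTS2 class, rose by a log2 of 2.59. Fatty acid oxidation and peroxisomal matrix genes went both ways (12 higher, 11 lower of 23, camera adjusted p = 0.555), with FAA1, an acyl-CoA synthetase, at -2.97. Trehalose and glycogen genes (6 higher, 12 lower, 0.0716) were not called, with GAC1 at -2.79, nor were oxidative stress and glutathione genes (18 higher, 10 lower of 29, 0.309), with GSH1, which makes gamma-glutamylcysteine, at 3.67.

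The other lists were not called. Cell wall mannoproteins and flocculins had 12 higher and 11 lower of 26 (camera adjusted p = 0.879), with CIS3 at log2 3.82. Histone and replication genes had 19 higher and 14 lower of 38 (0.5), with the G1 cyclin CLN2 at 2.78. Sporulation and meiosis genes had 4 higher and 12 lower of 17 (0.0887), and SPS100 changed most. Mating type genes gave 2 higher and 3 lower of 7 for the a-specific list (0.622), with MFA1 at -1.72. All 4 alpha-specific genes were lower (0.063), with STE3 at -1.89. Haploid-specific genes had 5 higher and 4 lower of 10 (0.604), with FAR1 at 3.20.

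**Figure D3:**
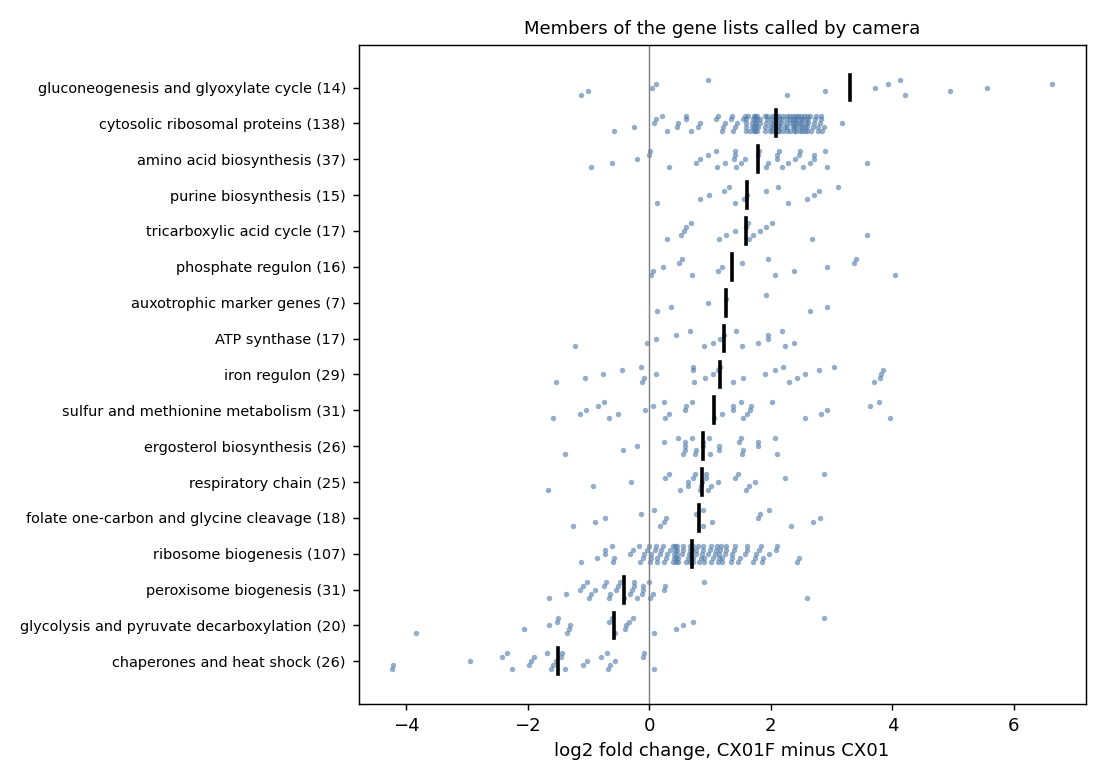
Log2 fold change, CX01F minus CX01, of each tested member (points, number of members in brackets) of the 17 lists called by camera with a preset correlation, with the median of each list as a bar. Cytosolic ribosomal proteins have a median of 2.09 and chaperones of -1.50, and none of the 17 calls held with an estimated correlation.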

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

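The alternatives were planned except the one without chromosomes XI and XV, chosen after seeing the data. The count of changed genes (5603) ranged from 5501 to 5617 when 1 library was left out, was 5553 with DESeq2 and 5599 with limma voom, and no summary count of genes moved by over 1.5 times. The count of lists did: 17 by camera, 0 with an estimated correlation and 35 with fry, which asks only whether a list's own genes move 1 way. Methanol and formaldehyde oxidation turned from lower (not called) to higher with fry (adjusted p = 2.39e-05, against 0.516 by camera). The cause was not tested. Library size only shifted the median log2 change of the tested genes by -0.207, gave 2221 higher and 3407 lower, and turned the sign of 150 calls. Leaving out XI and XV moved the log2 changes of the genes tested in both fits by a median of -0.116. Over all alternatives 793 values of named genes kept their direction and side of the threshold and 4 became called, all of PEX32. Of the lists' values 487 did so, 17 lost the call (each with an estimated correlation), 18 gained it and 1 reversed. With the replicate number as a replicate block 5619 genes were called. Same-numbered deviations correlated at 0.0242, 0.0785 and 0.0207, each library best with its own number. CX01 replicate 3 gave 0.0207 with its own number and 0.0196 with CX01F replicate 1. Correlations this small do not show that the numbers are pairs. DESeq2, limma voom and glmTreat (1689 genes at 2-fold) give no list values. Depth limits mainly genes near the floor of 0.0475 to 0.0582 CPM.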

Other observations

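The lists of this paragraph, and the genes of this part that the fixed rule does not name, were chosen after the data were seen, and the adjusted p of a list is over 8 lists. Aminoacyl-tRNA synthetases, which charge tRNAs, were higher in 19 of 20 cases and lower in 0, with a median log2 change of 1.55 (camera adjusted p = 9.94e-06, adjusted p = 0.125 with an estimated correlation) and KRS1 at 3.62. Translation factors had 24 higher and 3 lower of 28 (0.000339, and adjusted p = 0.125 with an estimated correlation), with YEF3 at 2.52. Vacuolar ATPase genes had 14 higher and 1 lower of 17 (0.00417, and adjusted p = 0.293 with an estimated correlation), with VMA7 at 1.21. Proteasome subunits had 6 higher and 25 lower of 34 (0.00353, and adjusted p = 0.409 with an estimated correlation), with RPN8, on XV, at -1.47. Autophagy genes had 8 higher and 24 lower of 34 (0.00417, and adjusted p = 0.125 with an estimated correlation), with ATG8 at -1.58. RNA polymerase III subunits (6 higher, 4 lower of 10, camera adjusted p = 0.484) had RPO31, on XV, at -1.24, and fatty acid synthesis (7 higher, 3 lower of 10, 0.163) had ELO3 at 2.67. The Gal4 targets had 6 higher and 1 lower of 8 tested, but this list holds GAL2, GAL3 and GAL80, whose rise prompted it, so no test of it is given. JEN1, a lactate and pyruvate transporter, on XI, was at 4269 ± 13.7 CPM in CX01F and 4151 ± 24.4 CPM in CX01 (edgeR adjusted p = 0.188).

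In the 3 patterns below, the tests were chosen after the result was seen, except the correction for GC content and coding length. Of the splits of the 6 libraries into 3 and 3, those for the counts of changed genes and of lists were planned before they were run.

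The split by strain called 5603 genes and the other 9 splits called 0 by edgeR, with 0 to 3 genes at an unadjusted p under 0.05. For genes higher, lower and changed at least 2-fold the strain split gave 2787, 2816 and 1878, against 0 in the others, so 1 of the 10 splits gave as many in each case. For lists called by camera 2 of the 10 splits gave 17 or more, the highest other being 18. With 10 splits no share can fall under 0.05. The mixed splits hold the strains in unequal numbers. Part of the strain difference stays between their groups, and the rest counts as spread within them. That spread holds down the edgeR calls of each mixed split, so the 0 calls there are no support for the 5603.

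Coding genes of chromosomes XI and XV lay lower in CX01F by -0.94 (95% bootstrap interval -1.04 to -0.87) and -0.98 (-1.06 to -0.91) than those of the other chromosomes. A trend with GC content and coding length, fitted on 5853 genes, left a shift of -0.97 on the chromosome nearer to 0, so it does not account for the difference. A fall in a subset of genes would leave the upper percentiles in place, but the smallest shift over 5 percentiles was -0.86. The shift held along both chromosomes, with -0.80 in the third nearest to 0, which is consistent with a different number of copies of XI and XV in the strains, near 2-fold. Whether the parent may have gained copies or the evolved strain lost them cannot be read from expression, and other strain differences stay open.

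GAL2, GAL3 and GAL80, genes of galactose uptake and its regulators, were 677-fold, 63.9-fold and 11.2-fold higher in CX01F, chosen after their values were seen. Extra copies of their regions would raise the neighbours, but the 18 nearest tested coding genes had a median of 0.23 (bootstrap SE 0.332), although YDR010C beside GAL3 and SUR7 beside GAL80 rose by 6.51 and 4.08. This median pools the neighbours of all 3 genes. It argues against extra copies of the regions together, but by itself not of a single region or of a gene without its neighbours. The neighbours of GAL2, 3 on each side, changed by -0.68 to 1.21 on the log2 scale, against 9.40 for GAL2. These values argue against extra copies of the GAL2 region as the source of its rise. Beside GAL3 and GAL80 a neighbour rose as well, so extra copies of single regions stay open there. GAL1, GAL7 and GAL10, the enzymes of galactose use, had 1 to 24 counts in each library of both strains, with at most 0.377 CPM of the unscaled total in a CX01F library, which decides nothing about Gal4 if the genes are missing in both strains. Of the other textbook targets of the activator Gal4, 3 of 4 were higher (GCY1, MTH1 and PCL10) while FUR4 fell by 0.48. Of all 6129 tested genes 2787 were called higher, so a count of 3 of 4 says little by itself. Higher activity at some Gal4 targets may be part of the change, and it was not settled by this count.

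SCR1, RPR1 and NME1, noncoding RNAs of the signal recognition particle, RNase P and RNase MRP, fell by 4.34, 3.36 and 1.64 on the log2 scale. Of 134 tRNA genes 94 were lower and 15 higher (median log2 change -1.33, median level 0.42 CPM), while the 79 snoRNA and snRNA genes, also mostly without poly(A) tails, went both ways (29 higher, 39 lower, median log2 change -0.17), near the median of -0.28 of coding genes under 400 nt. Loss of short transcripts would lower the shortest most, but SCR1, the longest, fell further than NME1, the shortest (difference -2.70, SE 0.136). A uniformly lower yield of RNA without a poly(A) tail as the whole cause would lower the 3 alike if all their reads came from these RNAs. Their range was 19.8 times its standard error. The falls also followed the level in CX01, at 365, 67.5 and 6.48 CPM for SCR1, RPR1 and NME1. Neither comparison separates length or yield from level, so neither rules out its cause. The labels give no library batch or selection step, so a preparation difference that touches some of these RNAs between the strains' libraries cannot be told apart from the strains, and a lower level in the cells may equally be involved.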
